A study of Homo sapiens with 12 samples.

How the data were processed

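The series holds 12 RNA-seq libraries from 3 clonal lines of HEK293 cells, each transfected with siRNA against SUPT4H1 or with scrambled siRNA, with 2 libraries in each of the 6 groups. Per the labels' protocols, RNA was extracted 72 hours after transfection at 100 nM from 750000 cells per sample, diluted ERCC spike-in RNA was added to each lysate, ribosomal RNA was depleted, and stranded libraries were made from total RNA. Per the labels, the RNA integrity number (RIN) lay between 9.3 and 10.0, knockdown libraries received ERCC mix 1 and scrambled libraries mix 2.

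The deposited table holds an expected (estimated) count per feature and library for 57946 features, of which 57853 are endogenous genes, 92 are ERCC transcripts and 1 is EGFP. The submitters' processing notes name FastQC 0.11.5, STAR, Salmon, MultiQC, R 3.4.3 and the build GRCh38.p10, without saying how transcript estimates became gene values or which annotation was used. The deposited estimated counts are not whole numbers, even for single-transcript spike-ins, so they may carry a scaling for transcript length by a factor near 1, which no label states. Symbols and biotypes were those of the deposited table. Positions, lengths and GC content were taken from GENCODE 29 on GRCh38, which held 57447 of the endogenous identifiers (99.3%). The library totals lay between 33209532 and 89479549 estimated counts (median 52791681). Replicates differed by a chi-square per gene of at least 16.1 (highest 92.6), and 0 genes with at least 20 counts had identical values in both libraries of a group, so the libraries of a group were not copies of each other, and pairs across groups were not compared.

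The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Estimated counts were rounded and analysed with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): genes were kept by filterByExpr, which left 21553, library sizes were scaled by TMM over endogenous genes, and a model with 1 mean per group (6 residual degrees of freedom) was fitted to all 12 libraries with the quasi-likelihood test. The biological coefficient of variation was 17.4% and the prior degrees of freedom 2.71. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were knockdown minus scrambled as the mean of the 3 lines and in each line, the mean response of both DARP lines minus that of the EGFP line, and each DARP line minus the EGFP line with scrambled siRNA, where a gene counted if it passed in both lines with the same direction. Values per library are TMM-scaled CPM.

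Of 33 gene lists, 31 had at least 5 tested members and were tested with camera at a preset correlation of 0.01 on log2 CPM, with adjustment over the lists. The lists were elongation factors, RNA polymerase II subunits, RNA polymerase I and III subunits, replication-dependent histones, immediate early genes, p53 targets, ATF4 targets of the integrated stress response, unfolded protein response targets, heat shock genes, proteasome subunits, autophagy genes, nucleoporins, RNA-binding proteins linked to ALS, repeat-expansion disease genes, cytosolic ribosomal proteins, ribosome biogenesis, mitochondrially encoded mRNAs, nuclear-encoded oxidative phosphorylation, cholesterol synthesis, glycolysis and hypoxia targets, interferon-stimulated genes, G1/S genes, G2/M genes, SMAD/TGF-beta and matrix genes, RNA polymerase III transcripts, small nuclear RNAs, long noncoding RNAs, neuron-like genes, RNAi machinery, and markers of fibroblasts, of blood and immune cells, of keratinized or cervical epithelium, and of endothelial and hepatic cells. The named genes were SUPT4H1, SUPT5H, C9orf72 and EGFP, the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM and the same sign in all 3 lines, and up to 2 rises and 2 falls of each list. Other members named beside a list, such as SMCR8, follow from the same rule. KRT17, whose list was too small to test, was named after its values were seen.

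Spike-in scaling used ERCC subgroup B, whose transcripts have equal nominal amounts in both mixes. The membership of the 4 subgroups of 23 transcripts was written from general knowledge before the data were examined, since no label gives it. The log2 of endogenous counts over subgroup B counts was compared between treatments by an exact two-sided permutation test within lines, with adjustment over 9 feature classes or 6 class ratios. For the same contrast on the spike-in scale, edgeR library sizes were set by subgroup B counts. Fold changes were set against genomic length by Spearman's rho across genes. Calls shared by comparisons with the same EGFP libraries were set beside 20 simulations of unchanged groups.

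The steps were tested on simulated data, with 200 changed genes per comparison, drawn from genes with a mean of at least 1 CPM. Each simulated gene had the same biological variation in all groups. For the mean of the lines (21020 genes), 79.1%, 94.0% and 98.5% of genes changed 1.5-, 2- and 4-fold were recovered, with 5 false among 186 calls. For 1 line (21050 genes) these were 19.4%, 65.7% and 93.9%, with 5 false among 124 calls, and for the interaction (21017 genes) 6.0%, 65.7% and 97.0%, with 7 false among 119. For both DARP lines against the EGFP line (20953 genes) they were 17.9%, 68.7% and 92.4%, with 2 false among 121. All 3 lists shifted by 0.5 log2 were called and 0 lists without shared members, and rho was -0.784 with a simulated trend and 0.009 without. Genes were simulated independently of each other, so these results do not test calls of lists whose members are correlated.

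Alternatives were DESeq2 1.42.0 with a local dispersion fit, limma-voom, DESeq2 size factors, no filter on low counts, a log2 fold change of at least 1, RIN as a covariate, the replicate number as a block, ERCC scaling, an estimated correlation and fry for lists, other length measures, each line's own 4 libraries, and each library left out in turn. Alternatives without the 2 knockdown libraries of lowest RIN, without DARP line 1, without the 2 scrambled libraries with high HBB counts (at least 200), with only the 6 DARP libraries with high HBB counts, with reversed mix ratios, with GC content as a second variable, and with the block for the rho with length were chosen after seeing the data, as were the lists on the interaction. Near-identical gene copies are reported as uncertain, with the summed counts where pairs were named. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.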

Results

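Total RNA depleted of ribosomal RNA was sequenced from 3 clonal lines of HEK293, an established human embryonic kidney cell line. The EGFP line expressed EGFP alone, and DARP lines 1 and 2 (named DARP-EGFP lines in the labels) expressed EGFP fused to dipeptide repeats encoded by 71 G4C2 repeats, the hexanucleotide that is expanded at C9orf72 in amyotrophic lateral sclerosis (ALS). Each line received siRNA against SUPT4H1 or a scrambled siRNA at 100 nM, and RNA was taken 72 hours later from 750000 cells per sample. Each of the 6 groups held 2 libraries, so each treatment had 6 libraries. The deposited values were estimated counts per gene, and they summed to between 33209532 and 89479549 per library (median 52791681). In the EGFP line the totals were 89479549 and 73477160 in the scrambled and 44563391 and 44836422 in the knockdown libraries. In DARP line 1 they were 86263057 and 43547921 against 46322432 and 33209532, and in DARP line 2 56878954 and 69937083 against 75253642 and 48704408. Between 44.5% and 52.8% of the counts of a library fell on RN7SK, RN7SL1 and RN7SL2, abundant small RNAs made by RNA polymerase III, and between 30.6% and 41.8% on protein-coding genes. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries. Unless stated otherwise, values are log2 fold changes with their standard errors from edgeR's quasi-likelihood test on 21553 genes, for the mean of the 3 lines (n = 6 libraries per treatment), and p-values are Benjamini-Hochberg adjusted.

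SUPT4H1, which encodes the SPT4 subunit of the elongation factor DSIF, was the gene targeted. It measured 36.6 ± 5.37 CPM (counts scaled to a common library size, mean ± SD, n = 6) in the scrambled libraries and 2.63 ± 0.338 CPM in the knockdown libraries, a change of -3.80 ± 0.08 (adjusted p = 2.74e-07). The scrambled libraries lay between 31.0 and 43.3 CPM and the knockdown libraries between 2.41 and 3.31 CPM, so every library matched its label. The change was -4.09 ± 0.15 in the EGFP line, -3.63 ± 0.15 in DARP line 1 and -3.69 ± 0.14 in DARP line 2 (n = 2 per group). SUPT5H, which encodes the partner subunit SPT5, measured 0.05 ± 0.05 (adjusted p = 0.59), and C9orf72 measured 0.07 ± 0.12 (adjusted p = 0.729). The EGFP feature measured -0.28 ± 0.20 in the EGFP line, 0.53 ± 0.20 in DARP line 1 and 0.31 ± 0.20 in DARP line 2, and its mean of 0.19 ± 0.12 did not pass (adjusted p = 0.265). Scaled to ERCC subgroup B spike-in counts instead, these means were -0.55 ± 0.17 (adjusted p = 0.016) for SUPT5H, -0.50 ± 0.13 (adjusted p = 0.00851) for C9orf72 and -0.42 ± 0.14 (adjusted p = 0.0223) for the EGFP feature, and all 3 passed. On that scale the median of all tested genes was -0.598, near the values of SUPT5H and C9orf72. The scale moved the median gene by -1.006 in the EGFP line and by -0.348 and -0.397 in DARP lines 1 and 2. The EGFP feature therefore fell most in the EGFP line on that scale, and its mean does not describe the DARP lines. On the scale of endogenous genes, the EGFP feature stood at 23.1 ± 3.2 CPM in the scrambled libraries of the EGFP line, 225 ± 0.287 in DARP line 1 and 311 ± 37.5 in DARP line 2 (SD, n = 2). In GENCODE 29 coordinates on GRCh38, the endogenous genes are SUPT4H1 (ENSG00000213246, chromosome 17, 58345175 to 58353093), SUPT5H (ENSG00000196235, chromosome 19, 39436156 to 39476670) and C9orf72 (ENSG00000147894, chromosome 9, 27546545 to 27573866).

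**Figure D1:**
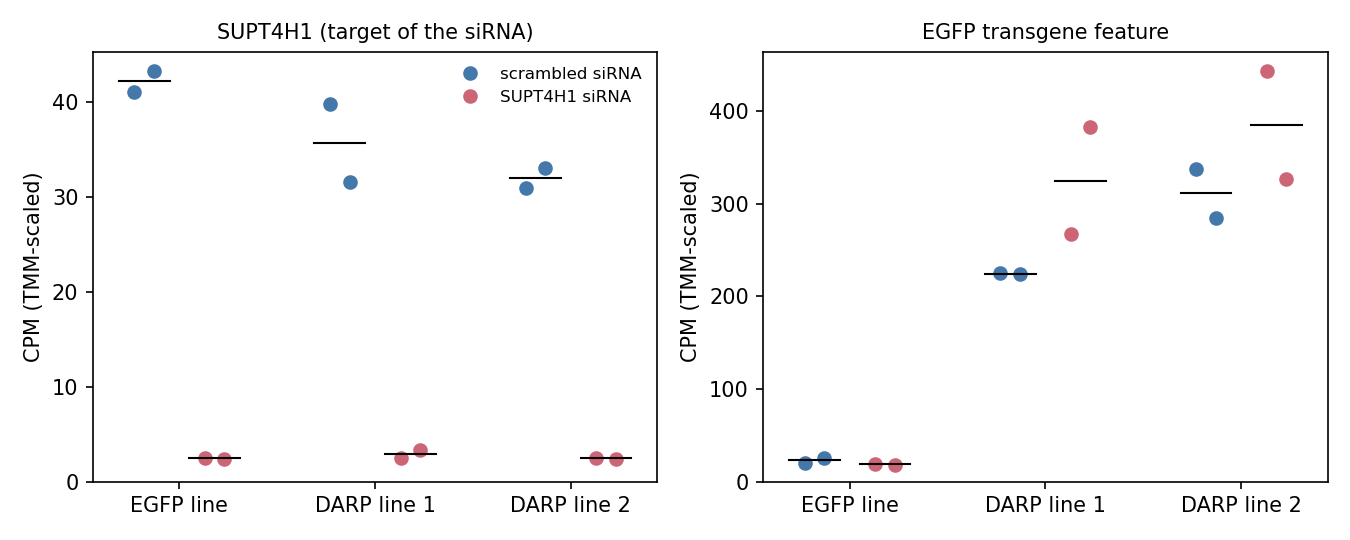
TMM-scaled CPM of SUPT4H1 (left) and of the EGFP feature (right) in each of the 12 libraries, by line and siRNA, with points for libraries and bars for group means. SUPT4H1 lay between 2.41 and 3.31 CPM in the 6 knockdown libraries and between 31.0 and 43.3 CPM in the 6 scrambled libraries.

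After SUPT4H1 knockdown, transcripts of the cell-cycle inhibitor CDKN1A rose by 1.20 ± 0.05 and those of the growth arrest gene GADD45B by 1.78 ± 0.09. Those of the stress-response factor ATF4 changed by -1.39 ± 0.06 and those of the cystine transporter SLC7A11 by -2.01 ± 0.07. In all, 6149 genes passed the threshold, 2889 up and 3260 down. Of these, 175 rose and 291 fell by at least 2-fold, and 91.2% had the same sign in all 3 lines. The genes were chosen on the mean of the same lines, so part of that agreement follows from the choice. All these fold changes are relative to the typical gene. Scaled to spike-in RNA instead, the median gene of the same comparison moved by a further -0.58, and 12460 genes passed, 99 up and 12361 down. The spike-in count was 7005 with the replicate number as a block. Over all ERCC transcripts it was 19039 at the labelled mix ratio. The subgroup ratios ran opposite to the labelled mixes (A over B at -1.95 where 2.0 was nominal). At the reversed ratio, added after the data had been seen, the count was 10715. A rise that turned into a fall on the spike-in scale is given with both values.

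Among the 10 largest rises chosen by the rule fixed beforehand, ACTA2 (1.73 ± 0.07) and GADD45B (1.78 ± 0.09) rose most among protein-coding genes with a mean of at least 5 CPM, the same sign in all 3 lines and no near-identical copy. They were followed by CDKN1A (1.20 ± 0.05), the lysosomal sialidase gene NEU1 (1.12 ± 0.08), TLCD1 (1.11 ± 0.06), UBALD2 (1.01 ± 0.11) and C17orf89 (0.99 ± 0.06). CDKN1A went from 22.4 ± 2.99 to 52.7 ± 13.3 CPM and GADD45B from 7.72 ± 1.56 to 27 ± 8.76 CPM (SD, n = 6). These 7 genes also lay above their scrambled level on the spike-in scale, for example CDKN1A at 0.62 and GADD45B at 1.20. After SUPT4H1, the largest falls under the same limits were those of the zinc finger gene ZNF711 (-1.67 ± 0.12), ZCCHC12 (-1.65 ± 0.06), the metallothionein MT1X (-1.45 ± 0.11) and ATF4 (-1.39 ± 0.06). They were followed by those of the sterol sensor INSIG1 (-1.33 ± 0.09), ADAMTS1 (-1.23 ± 0.10), the glucocorticoid-induced gene TSC22D3 (-1.19 ± 0.11) and the proline synthesis gene PYCR1 (-1.14 ± 0.08). ATF4 went from 197 ± 19.5 to 74.9 ± 2.67 CPM and INSIG1 from 103 ± 22.2 to 40.7 ± 7.62 CPM (SD, n = 6). Adjusted p-values of these named genes lay between 3.95e-06 and 0.000406. The rule also named 4 genes with near-identical copies, whose values are uncertain because counts can be split between copies. HIST2H2AA3 measured 5.36 ± 0.90, but its sum with HIST2H2AA4 differed by -0.16 ± 0.07. SMIM11A measured -1.49 ± 0.26, but its sum with SMIM11B differed by -0.37 ± 0.04. HBA2 measured 5.01 ± 1.02, and its sum with HBA1 differed by 4.94 ± 1.62. The histone gene HIST1H2AL measured 1.00 ± 0.07, and its copies were not summed. Globin counts followed the library and not the treatment alone. HBB counts were between 1846 and 3718 in all 6 knockdown libraries and in 2 scrambled libraries, and between 17 and 30 in the other 4. Positions on GRCh38 are CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), GADD45B (ENSG00000099860, chromosome 19, 2476122 to 2478259), ATF4 (ENSG00000128272, chromosome 22, 39519695 to 39522685) and INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235).

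Targets of p53 had the lowest camera p of the lists that moved up, though not the largest median. Of 24 tested, 18 rose, 1 fell and 5 did not pass (19 and 1 adjusted over the list alone). Their median was 0.42, or -0.17 on the spike-in scale (camera adjusted p = 5.13e-10, and adjusted p = 0.222 with an estimated correlation). The members with the largest rises were CDKN1A (1.20 ± 0.05) and the metabolic regulator TIGAR (0.99 ± 0.09), and the death receptor gene TNFRSF10B (-0.17 ± 0.04) fell. Medians were 0.42 in the EGFP line, 0.46 in DARP line 1 and 0.46 in DARP line 2. Targets of ATF4, which drive amino acid synthesis and transport in the integrated stress response, moved the other way. Of 27, 1 rose, 22 fell and 4 did not pass (1 and 22 adjusted over the list alone). Their median was -0.57, or -1.16 on the spike-in scale (camera adjusted p = 3.30e-09, and adjusted p = 0.222 with an estimated correlation). SLC7A11 (-2.01 ± 0.07) and ATF4 (-1.39 ± 0.06) fell most, and ATF5 (0.45 ± 0.09, but -0.14 on the spike-in scale) rose. Medians for this list were -0.42 in the EGFP line, -0.62 in DARP line 1 and -0.54 in DARP line 2. HBB counts, given above, were high in all 6 knockdown libraries while these lists moved, and in the 2 scrambled libraries with high HBB counts SUPT4H1 stood at 31.6 and 31.0 CPM.

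Several lists for protein turnover and respiration moved up. Of 31 proteasome subunits, 17 rose, 0 fell and 14 did not pass (19 and 0 adjusted over the list alone). Rises included PSMD12 (0.60 ± 0.08, but -0.003 on the spike-in scale) and PSMB4 (0.39 ± 0.05, but -0.21 on the spike-in scale). Their median was 0.23, or -0.38 on the spike-in scale (camera adjusted p = 1.71e-06, and adjusted p = 0.511 with an estimated correlation). Of 13 mitochondrially encoded mRNAs, 12 rose, 0 fell and 1 did not pass (12 and 0 adjusted over the list alone). Their median was 0.59, or 0.03 on the spike-in scale (camera adjusted p = 9.98e-06, and adjusted p = 0.511 with an estimated correlation). MT-ND4L (0.96 ± 0.18) and MT-ATP8 (0.70 ± 0.12) rose most. Medians of these mRNAs were 0.08 in the EGFP line, 1.34 in DARP line 1 and 0.44 in DARP line 2. DARP line 1 knockdown replicate 1, the library of lowest RIN (9.3), also had the highest share of counts on mitochondrial features, 2.59%, beside 1.83% in replicate 2. Of 41 nuclear-encoded genes of oxidative phosphorylation, 15 rose, 0 fell and 26 did not pass (17 and 0 adjusted over the list alone). They included NDUFB3 (0.44 ± 0.09, but -0.14 on the spike-in scale) and ATP5C1 (0.43 ± 0.12, but -0.16 on the spike-in scale). The list's median was 0.14, or -0.43 on the spike-in scale (camera adjusted p = 6.13e-05, and adjusted p = 0.637 with an estimated correlation). Genes of G2/M and mitosis moved down: of 36, 1 rose, 15 fell and 20 did not pass (1 and 16 adjusted over the list alone). Their median was -0.13 (camera adjusted p = 0.000113, and adjusted p = 0.251 with an estimated correlation). The mitotic kinase AURKB (-0.71 ± 0.05) and the centromeric histone CENPA (-0.57 ± 0.07) fell, and PTTG1 (0.34 ± 0.09, but -0.23 on the spike-in scale) rose. Medians of this list were -0.11 in the EGFP line, -0.36 in DARP line 1 and 0.00 in DARP line 2.

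Markers of other cell types were tested as lists of their own. Of 6 fibroblast markers, 0 rose, 3 fell and 3 did not pass (0 and 5 adjusted over the list alone). Their median was -0.53 (camera adjusted p = 0.0125, and adjusted p = 0.511 with an estimated correlation), and COL3A1 (-0.87 ± 0.25) and COL1A1 (-0.62 ± 0.15) fell from 0.346 and 1.08 CPM in the scrambled libraries. Of 5 blood and immune markers, 2 rose, 0 fell and 3 did not pass (4 and 0 adjusted over the list alone). Their median was 1.69, or 1.09 on the spike-in scale (camera adjusted p = 0.011, and adjusted p = 0.222 with an estimated correlation). CD68 (1.69 ± 0.19), a lysosomal gene of macrophages that other cells also express, went from 0.921 ± 0.279 to 2.93 ± 0.805 CPM (SD, n = 6), and CORO1A (0.51 ± 0.13, but -0.10 on the spike-in scale) rose. HBB is itself a tested member of this list, so the list's median and camera p are not separate from the globin counts. HBB counts, given above, were high in the same 6 knockdown libraries and in 2 scrambled libraries. Of 12 keratinized or cervical epithelium markers 3 were tested, KRT17 at 0.36 ± 0.19, S100A2 at 0.10 ± 0.26 and SFN at 0.02 ± 0.12, and none passed. Of 12 endothelial and hepatic markers 0 were tested, since none had enough counts for the filter.

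**Figure D2:**
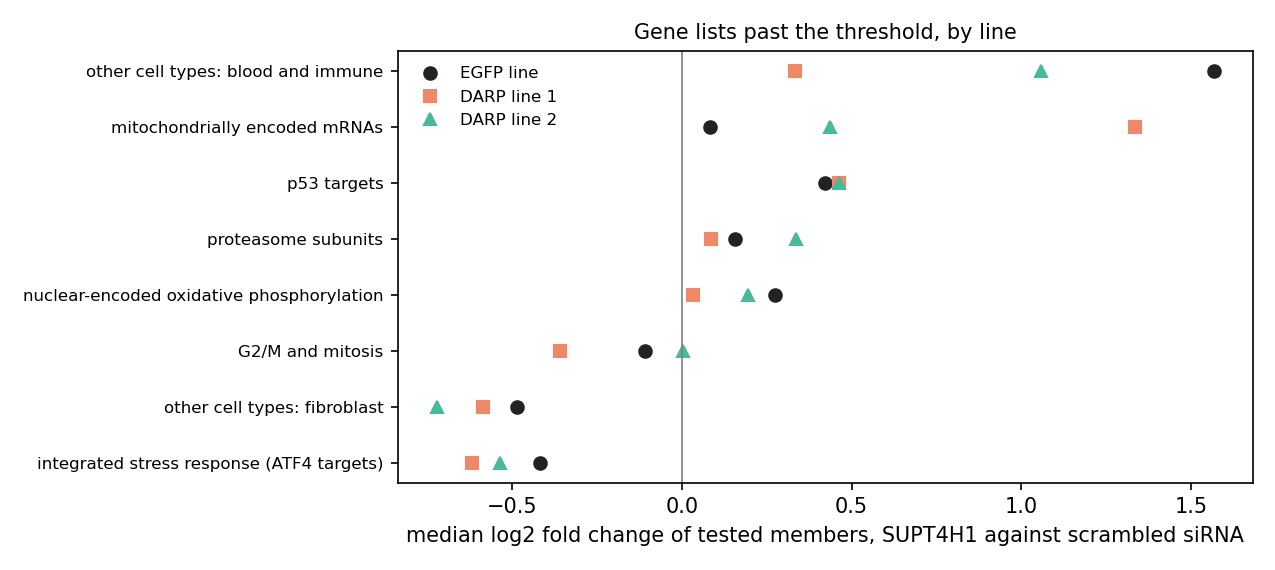
Median log2 fold change of the tested members, SUPT4H1 siRNA against scrambled siRNA on the TMM scale, for the 8 gene lists past the camera threshold, with 1 point per line. Targets of p53 lay at 0.42 in the EGFP line and 0.46 in both DARP lines, and ATF4 targets between -0.62 and -0.42.

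Lists for the transcription machinery held members that rose and members that fell, and no list passed. Of 27 elongation factors, 9 rose, 4 fell and 14 did not pass (9 and 4 adjusted over the list alone), with a camera adjusted p of 0.209. The list holds SUPT4H1 itself, at -3.80, as 1 of the 4 that fell. Without it, 9 of 26 rose and 3 fell. HEXIM1 (0.53 ± 0.12, but -0.08 on the spike-in scale), an inhibitor of the kinase P-TEFb, and the PAF1 complex gene CTR9 (0.45 ± 0.08, but -0.14 on the spike-in scale) rose, and NELFA (-0.33 ± 0.03) fell. Of 12 RNA polymerase II subunits, 4 rose, 1 fell and 7 did not pass (4 and 1 adjusted over the list alone). POLR2L (0.60 ± 0.09, but -0.01 on the spike-in scale) rose and POLR2G (-0.27 ± 0.08) fell (camera adjusted p of the list = 0.0678). Of 15 subunits of RNA polymerases I and III, 2 rose, 3 fell and 10 did not pass (2 and 3 adjusted over the list alone). They included POLR1C (0.31 ± 0.08, but -0.29 on the spike-in scale), POLR3K (-0.47 ± 0.10) and POLR1E (-0.40 ± 0.04) (camera adjusted p of the list = 0.947). Of 52 replication-dependent histones, whose near-identical copies make single members uncertain, 8 rose, 12 fell and 32 did not pass (9 and 13 adjusted over the list alone). They included HIST1H2AL (1.00 ± 0.07) and HIST1H3F (-0.56 ± 0.10) (camera adjusted p of the list = 0.558). Of 27 immediate early genes, 12 rose, 7 fell and 8 did not pass (13 and 7 adjusted over the list alone). FOSB (0.83 ± 0.13) rose and the growth regulator MYC (-1.03 ± 0.06) fell (camera adjusted p of the list = 0.126). Of 13 genes of the RNAi and microRNA machinery, 3 rose, 1 fell and 9 did not pass (4 and 1 adjusted over the list alone). TNRC6A (0.36 ± 0.05, but -0.23 on the spike-in scale) rose and DGCR8 (-0.27 ± 0.04) fell (camera adjusted p of the list = 0.429). For elongation factors the median (0.10) and the mean (-0.04) differed in sign, but without SUPT4H1 they were 0.11 and 0.11. They also differed in sign for nucleoporins (0.01 and -0.01) and repeat-expansion disease genes (0.04 and -0.02), while camera's direction was up for subunits of RNA polymerases I and III (median -0.02) and for small nuclear RNAs (median -0.09).

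Lists for protein folding and nuclear transport did not pass either. Of 20 targets of the endoplasmic reticulum unfolded protein response, 4 rose, 2 fell and 14 did not pass (5 and 3 adjusted over the list alone). CALR (0.47 ± 0.06, but -0.13 on the spike-in scale) rose and DERL3 (-0.70 ± 0.06) fell (camera adjusted p of the list = 0.542). Of 20 cytosolic heat shock genes, 9 rose, 4 fell and 7 did not pass (10 and 6 adjusted over the list alone). The co-chaperone DNAJA1 (0.86 ± 0.08) rose and FKBP4 (-0.29 ± 0.05) fell (camera adjusted p of the list = 0.103). Of 23 autophagy genes, 7 rose, 2 fell and 14 did not pass (7 and 2 adjusted over the list alone). MAP1LC3B (0.69 ± 0.12) rose and WIPI1 (-0.47 ± 0.12) fell (camera adjusted p of the list = 0.182). SMCR8 (0.56 ± 0.11, but -0.05 on the spike-in scale), whose protein binds the C9orf72 protein, rose. Of 31 nucleoporins and nuclear transport genes, 2 rose, 4 fell and 25 did not pass (2 and 4 adjusted over the list alone). They included NUP214 (0.38 ± 0.08, but -0.19 on the spike-in scale) and the small GTPase RAN (-0.53 ± 0.10) (camera adjusted p of the list = 0.846). Of 20 RNA-binding proteins linked to ALS, 1 rose, 3 fell and 16 did not pass (0 and 2 adjusted over the list alone), and HNRNPA3 (-0.40 ± 0.08) and HNRNPA2B1 (-0.23 ± 0.06) fell (camera adjusted p of the list = 0.738). Of 21 genes of repeat-expansion diseases, 3 rose, 1 fell and 17 did not pass (2 and 1 adjusted over the list alone). CSTB (0.27 ± 0.05, but -0.32 on the spike-in scale) and ATXN10 (0.24 ± 0.05, but -0.35 on the spike-in scale) rose and CNBP (-0.49 ± 0.07) fell (camera adjusted p of the list = 0.728).

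Translation and metabolism lists held members that moved both ways. Of 78 cytosolic ribosomal protein genes, 5 rose, 20 fell and 53 did not pass (7 and 23 adjusted over the list alone). They included RPL28 (0.54 ± 0.09, but -0.06 on the spike-in scale) and RPL13 (-0.72 ± 0.08) (camera adjusted p of the list = 0.121). Of 30 ribosome biogenesis genes, 1 rose, 5 fell and 24 did not pass (1 and 4 adjusted over the list alone). They included UTP4 (0.29 ± 0.07, but -0.31 on the spike-in scale) and the nucleolar GNL3 (-0.57 ± 0.08) (camera adjusted p of the list = 0.112). Of 27 SREBP2 targets of cholesterol synthesis, 3 rose, 12 fell and 12 did not pass (3 and 13 adjusted over the list alone). INSIG1 (-1.33 ± 0.09) and HMGCS1 (-0.72 ± 0.05) fell and TM7SF2 (0.88 ± 0.09) rose (camera adjusted p of the list = 0.103). Of 27 glycolysis and hypoxia targets, 6 rose, 5 fell and 16 did not pass (7 and 5 adjusted over the list alone). The peptide hormone gene ADM (0.96 ± 0.05) rose and ENO1 (-0.38 ± 0.06) fell (camera adjusted p of the list = 0.542). Of 28 interferon-stimulated genes, 5 rose, 4 fell and 19 did not pass (5 and 4 adjusted over the list alone). IFI27 (0.84 ± 0.18) rose and IFITM1 (-0.84 ± 0.12) fell (camera adjusted p of the list = 0.355). Of 32 G1/S and DNA replication genes, 6 rose, 9 fell and 17 did not pass (7 and 13 adjusted over the list alone). The polymerase clamp PCNA (0.41 ± 0.05, but -0.18 on the spike-in scale) rose and CDT1 (-0.38 ± 0.05) fell (camera adjusted p of the list = 0.792). Of 21 SMAD/TGF-beta and extracellular matrix genes, 3 rose, 8 fell and 10 did not pass (4 and 9 adjusted over the list alone). ACTA2 (1.73 ± 0.07) and TAGLN (0.83 ± 0.17) rose and COL5A1 (-0.84 ± 0.23) fell (camera adjusted p of the list = 0.506).

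Among noncoding RNAs, NEAT1 (-1.14 ± 0.19) and MALAT1 (-0.69 ± 0.14), nuclear RNAs of paraspeckles and speckles, fell. Of 19 long noncoding RNAs, 4 rose, 7 fell and 8 did not pass (4 and 7 adjusted over the list alone), with SNHG5 (0.46 ± 0.09, but -0.11 on the spike-in scale) and TUG1 (0.44 ± 0.09, but -0.14 on the spike-in scale) up (camera adjusted p of the list = 0.547). Of 15 RNA polymerase III transcripts, 0 rose, 1 fell and 14 did not pass (0 and 0 adjusted over the list alone). The fall was that of RN7SL2 (-0.34 ± 0.11), which has near-identical copies (camera adjusted p of the list = 0.547). Of 15 spliceosomal and U7 small nuclear RNAs, which also have many copies, 0 rose, 1 fell and 14 did not pass (0 and 1 adjusted over the list alone). The member that fell was RNU5D-1 (-1.46 ± 0.36) (camera adjusted p of the list = 0.651). Medians of the small nuclear RNAs were 0.79 in the EGFP line, -0.23 in DARP line 1 and -0.56 in DARP line 2. Of 15 neuron-like genes, 1 rose, 6 fell and 8 did not pass (1 and 6 adjusted over the list alone). ELAVL3 (-2.37 ± 0.44) and GAP43 (-0.94 ± 0.13) fell and TUBB3 (0.42 ± 0.11, but -0.16 on the spike-in scale) rose (camera adjusted p of the list = 0.103).

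In the EGFP line alone 1663 genes passed (755 up, 908 down), in DARP line 1 1982 (836 up, 1146 down) and in DARP line 2 2818 (1267 up, 1551 down), with n = 2 libraries per group. With the replicate number as a block, 27, 60 and 520 genes passed in these lines. SUPT4H1, ATF4 and CDKN1A moved the same way in each line: ATF4 by -1.29, -1.56 and -1.33, and CDKN1A by 1.19, 1.45 and 0.97, in the EGFP line and DARP lines 1 and 2. The EGFP line and DARP line 1, which share no library, had 233 rises and 434 falls in common, where independent lists of these sizes would share 29.3 and 48.3. The calls of all lines used 1 estimate of spread per gene from all 12 libraries, which can raise the overlap above that of independent lists. The EGFP line and DARP line 2 shared 425 rises and 516 falls (44.4 and 65.3 for independent lists), and both DARP lines shared 374 rises and 581 falls (49.1 and 82.5). In all 3 lines separately, 172 genes rose and 333 fell. Across genes, Pearson's r between the lines' fold changes was 0.30 for the EGFP line and DARP line 1, 0.276 for the EGFP line and DARP line 2, and 0.303 for both DARP lines, and genes are not independent replicates. Counts in 1 line depended on single libraries, and where a library of that line's own groups is left out, its partner is assumed to vary like the other groups. The EGFP count was 90 without EGFP scrambled replicate 1, 95 without replicate 2, 79 without EGFP knockdown replicate 1 and 451 without replicate 2. It was 781 and 776 without DARP line 2 scrambled replicates 1 and 2, and 1077 without DARP line 2 knockdown replicate 2. The DARP line 1 count was 508 without its scrambled replicate 1, 782 and 1319 without its knockdown replicates 1 and 2. It was 1111 and 1131 without EGFP scrambled replicates 1 and 2, and 1088 without either scrambled replicate of DARP line 2. The DARP line 2 count was 437 and 347 without its scrambled replicates 1 and 2, 428 and 1016 without its knockdown replicates 1 and 2, and 1775 and 1793 without EGFP scrambled replicates 1 and 2. Fitted on its own 4 libraries, DARP line 1 gave 0 genes by edgeR with 2967 at an unadjusted p under 0.05. DESeq2 and limma-voom on all 12 libraries gave 2865 and 1924 for DARP line 1. EdgeR gave 1266 there with RIN as a covariate and 1192 without a filter on low counts. Leaving out the 2 scrambled libraries with high HBB counts left high HBB counts in every knockdown library and in no scrambled library. That alternative therefore cannot separate HBB counts from treatment. For 1703 genes called in the EGFP line from its own libraries, the median signed log2 fold change was 0.35 in all 8 DARP libraries. It was 0.38 in only the 6 DARP libraries with high HBB counts.

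Whether the response differed between the repeat-expressing lines and the EGFP line was tested as an interaction, the mean knockdown effect of both DARP lines minus that of the EGFP line. SUPT4H1 itself measured 0.43 ± 0.17 (adjusted p = 0.412), C9orf72 -0.43 ± 0.25 (adjusted p = 0.578) and the EGFP feature 0.70 ± 0.25 (adjusted p = 0.38). On the spike-in scale these were 1.07 ± 0.27, 0.21 ± 0.27 and 1.29 ± 0.29, without an adjustment over genes, and that scale moves the median gene by -1.006 in the EGFP line and by -0.348 and -0.397 in DARP lines 1 and 2. By edgeR 0 of 21553 genes passed, 2400 had an unadjusted p under 0.05, limma-voom also gave 0, and DESeq2 gave 282. Without DARP line 1 scrambled replicate 2 the edgeR count was 3, and without DARP line 1 knockdown replicate 1 it was 1. In data simulated for this comparison, edgeR recovered 6.0% of genes that differed 1.5-fold, 65.7% of those that differed 2-fold and 97.0% of those that differed 4-fold, with 21017 genes tested. The changed genes were drawn only from those with a mean of at least 1 CPM, so recovery among all tested genes can be lower. Of the 31 lists, tested on this contrast after the data had been seen, 9 passed with camera (5 without the 2 knockdown libraries of lowest RIN), among them mitochondrially encoded mRNAs (median 0.56, adjusted p = 4.15e-06) and cytosolic ribosomal proteins (median -0.25, adjusted p = 5.08e-07). With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05, the lowest adjusted p being 0.557, and fry gave 0 in 1 direction, with 5 at an unadjusted p under 0.05, and 1 in either direction.

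Per the labels, spike-in RNA was added to lysates of the same number of cells. If that held, counts per spike-in count give RNA relative to cells before the library steps, but cell number was not tested here. ERCC subgroup B has equal nominal amounts in both mixes, with a membership written from general knowledge that these data did not settle. Endogenous RNA per count of subgroup B was lower after SUPT4H1 knockdown, with a log2 difference of -0.64 ± 0.09 (SE). It stood at 64.0% of the scrambled level and was lower in all 3 lines (exact permutation within lines, two-sided p = 0.00926, n = 6 per treatment). Over all ERCC transcripts the log2 difference was -1.325 at the labelled mix ratio and, as an alternative added after the data had been seen, -0.547 at the reversed ratio. The difference over subgroup B was -0.84 in the EGFP line, -0.51 in DARP line 1 and -0.59 in DARP line 2, corresponding to 56.0%, 70.2% and 66.7%. Cytosolic ribosomal protein mRNAs fell to 61.4%, replication-dependent histones to 62.4%, RNA polymerase III transcripts to 63.0%, nuclear protein-coding genes to 65.8%, small nuclear RNAs to 70.1% and long noncoding RNA features to 57.8% of the scrambled level. Each of these classes had an adjusted p of 0.0208 over the 9 classes tested by the same exact permutation. Mitochondrially encoded mRNAs, at 87.5%, did not pass (-0.19 ± 0.16, exact permutation p = 0.389, n = 6 per treatment). Relative to nuclear protein-coding genes, mitochondrially encoded mRNAs were higher by 0.41 ± 0.08, in all 3 lines, with an exact permutation p of 0.00926 that became 0.0556 over the 6 ratios tested and so failed the correction. By line this ratio was higher by 0.16 in the EGFP line, 0.785 in DARP line 1 and 0.289 in DARP line 2. The smallest p that permutation within the 3 lines allows is 0.00926, and within 1 line it is 0.333, so lines were not tested singly. The labels give mix 1 to every knockdown library and mix 2 to every scrambled library, so a difference in the spike-in added would move with the treatment. The ratios of the other subgroups ran opposite to the labelled mixes, and subgroup A over B was -1.95 ± 0.04 where 2.0 was nominal. Between 16687 and 50931 subgroup B counts per library stood behind these values, 69.9% of them from 1 transcript.

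**Figure D3:**
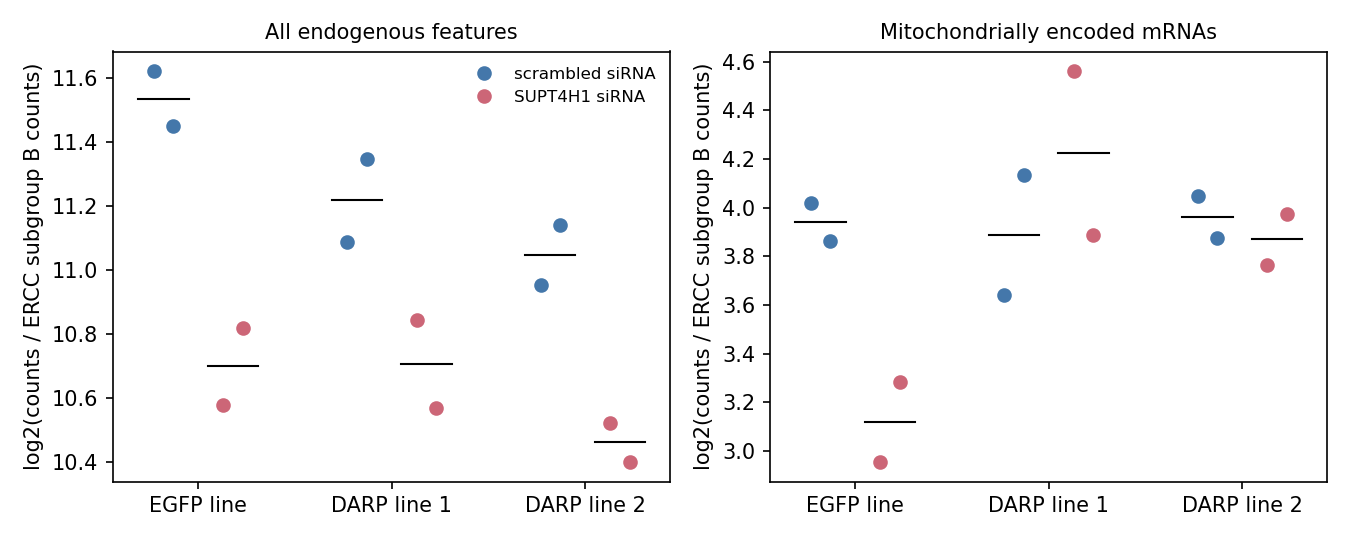
Log2 of counts per ERCC subgroup B count for all endogenous features (left) and for mitochondrially encoded mRNAs (right) in each of the 12 libraries, by line and siRNA, with points for libraries and bars for group means. All endogenous features differed by -0.84, -0.51 and -0.59 in the EGFP line and DARP lines 1 and 2, and mitochondrially encoded mRNAs differed by -0.82, 0.34 and -0.09.

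Since DSIF acts along the gene body, fold changes were compared with gene length. Across 13889 protein-coding genes, Spearman's rho between genomic length and the knockdown fold change was 0.005, and it was -0.027 in the EGFP line, 0.038 in DARP line 1 and 0.004 in DARP line 2. The quintile of shortest genes (median 5406.5 bp) had a median of -0.02 and the quintile of longest genes (median 176916.5 bp) a median of -0.01. In the shortest quintile 512 genes rose and 592 fell, and in the longest 404 rose and 489 fell. Fold changes were lower for genes of higher GC content (rho -0.203), and given GC content the partial rho with length was -0.082, an alternative added after the data had been seen. These values are across genes, which are not independent replicates.

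With scrambled siRNA, both DARP lines were compared with the EGFP line. Higher in both DARP lines were the neural transcription factor SOX11 (5.50 ± 0.16 in line 1 and 5.87 ± 0.16 in line 2) and the microtubule-binding MAP7D2 (5.27 ± 0.20 in line 1 and 5.86 ± 0.19 in line 2). The GABA receptor subunit gene GABRE (3.66 ± 0.31 in line 1 and 5.18 ± 0.30 in line 2), the lysosomal protease CTSZ (3.36 ± 0.19 in line 1 and 3.31 ± 0.19 in line 2) and DECR1 (2.74 and 3.34) were higher as well. The rule also named TXNIP (3.03 and 3.01), SYCE1L (2.51 and 3.38) and HIST1H2BI, which has near-identical copies and is uncertain (6.05 and 6.60). Lower in both were the metallothionein MT1X (-2.09 ± 0.19 in line 1 and -2.11 ± 0.19 in line 2) and TRMT61A (-1.47 ± 0.18 in line 1 and -1.88 ± 0.19 in line 2). ZNF711 (-0.84 and -2.88), ANXA1 (-0.62 and -2.23), ADI1 (-1.43 and -1.13), ZCCHC12 (-0.98 and -1.48), BTBD6 (-1.39 and -1.04) and MAPK8IP2 (-1.80 and -0.58) were lower as well. SOX11 stood at 0.286 CPM in the EGFP line, 13.1 in DARP line 1 and 16.9 in DARP line 2, and MT1X at 108, 25.3 and 25.0 CPM (means, n = 2). In all 2569 genes passed in both lines with the same direction, 1599 higher and 970 lower, and 102 passed in opposite directions. Lists of the same sizes drawn independently would share 319.9 and 213.6. With a log2 fold change of at least 1 in both lines, 425 genes were higher and 65 lower. In 20 simulations of unchanged groups against the same EGFP libraries, edgeR's highest shared count was 0, and part of the excess over independent lists can come from the shared controls, which are too few to be split. Where no gene changes, few can pass in either line, so the count of 0 does not measure that part. The covariance of both contrasts across genes was 0.236, against 0.0377 in the simulations, a difference of 0.198. Their correlation was 0.644, against 0.477. Each line is 1 clone, so differences between clones and effects of the transgene are not separated. The count was 899 and 1087 without EGFP scrambled replicates 1 and 2, 1471 without DARP line 1 scrambled replicate 1, and 1480 and 1530 without DARP line 2 scrambled replicates 1 and 2. It was 1345 without the 2 scrambled libraries with high HBB counts, which are DARP line 1 replicate 2 and DARP line 2 replicate 1.

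Proteasome subunits and ribosome biogenesis genes were lower in the DARP lines. Of 31 proteasome subunits, 0 were higher, 16 lower and 15 did not pass in the mean of both lines (0 and 25 adjusted over the list alone). They included PSMC4 (-0.68 and -0.67) and PSMA7 (-0.42 and -0.74) (camera adjusted p = 3.98e-07, and adjusted p = 0.487 with an estimated correlation). Of 30 ribosome biogenesis genes, 3 were higher, 17 lower and 10 did not pass in the mean of both lines (4 and 23 adjusted over the list alone). They included LTV1 (-0.46 and -1.41) and RRS1 (-0.68 and -1.06), with NOLC1 (0.57 and 0.30) higher (camera adjusted p = 6.07e-06, and adjusted p = 0.487 with an estimated correlation). Of 20 cytosolic heat shock genes, 2 were higher, 14 lower and 4 did not pass in the mean of both lines (3 and 15 adjusted over the list alone). DNAJA1 (-0.86 and -1.05) and DNAJB1 (-0.65 and -0.92) were lower and the small heat shock gene HSPB1 (1.86 and 2.22) was higher (camera adjusted p = 0.00135, and adjusted p = 0.551 with an estimated correlation). Of 20 RNA-binding proteins linked to ALS, 1 was higher, 6 lower and 13 did not pass in the mean of both lines (1 and 8 adjusted over the list alone). They included the splicing factors SRSF1 (-0.80 and -0.66) and HNRNPH1 (-0.70 and -0.49) (camera adjusted p = 0.00458, and adjusted p = 0.487 with an estimated correlation). Of 27 elongation factors, 0 were higher, 7 lower and 20 did not pass in the mean of both lines (0 and 9 adjusted over the list alone). They included NELFE (-0.26 and -0.95) and ELL2 (-0.30 and -0.29) (camera adjusted p = 0.00463, and adjusted p = 0.487 with an estimated correlation). Of 31 nucleoporins and nuclear transport genes, 3 were higher, 8 lower and 20 did not pass in the mean of both lines (4 and 11 adjusted over the list alone). NUP98 (-0.53 and -0.52) was lower and NUP133 (0.76 and 0.46) was higher (camera adjusted p = 0.00477, and adjusted p = 0.487 with an estimated correlation). RNA polymerase II subunits, with POLR2D (-0.40 and -0.45), had 4 of 12 lower (7 adjusted over the list alone). Subunits of RNA polymerases I and III, with POLR3C (-0.63 and -0.69), had 5 of 15 lower and 1 higher (6 and 1 adjusted over the list alone). G1/S genes, with RRM2 (-0.64 and -0.92), had 13 of 32 lower and 1 higher (13 and 1 adjusted over the list alone). Each of these 3 lists had a camera adjusted p of 0.0106, and adjusted p-values of 0.487, 0.487 and 0.613 with an estimated correlation. Glycolysis and hypoxia targets were higher: of 27, 12 were higher, 3 lower and 12 did not pass in the mean of both lines (12 and 5 adjusted over the list alone). They included P4HA1 (0.80 and 1.58) and PFKP (1.03 and 1.00) (camera adjusted p = 0.0154, and adjusted p = 0.656 with an estimated correlation). Of 15 neuron-like genes, 7 were higher, 2 lower and 6 did not pass in the mean of both lines (8 and 2 adjusted over the list alone). They included the neurofilament gene INA (3.13 and 4.08) (camera adjusted p = 0.0464, and adjusted p = 0.487 with an estimated correlation). Fewer members passed in each line singly with the same direction. Higher and lower ones then numbered 0 and 6 for proteasome subunits, 2 and 9 for ribosome biogenesis genes, 1 and 5 for heat shock genes and 0 and 4 for RNA-binding proteins linked to ALS. They numbered 0 and 2 for elongation factors, 3 and 4 for nucleoporins, 0 and 2 for RNA polymerase II subunits and 0 and 1 for subunits of RNA polymerases I and III. For the remaining lists they numbered 0 and 6 for G1/S genes, 6 and 0 for glycolysis and hypoxia targets and 1 and 0 for neuron-like genes. Medians in DARP lines 1 and 2 were -0.25 and -0.45 for proteasome subunits, -0.25 and -0.57 for ribosome biogenesis genes, -0.13 and -0.65 for heat shock genes and -0.24 and -0.36 for RNA-binding proteins linked to ALS. They were -0.16 and -0.15 for elongation factors, -0.08 and -0.31 for nucleoporins, -0.34 and -0.36 for RNA polymerase II subunits and -0.17 and -0.41 for subunits of RNA polymerases I and III, and -0.16 and -0.14 for G1/S genes, 0.15 and 0.34 for glycolysis and hypoxia targets and 0.15 and 0.88 for neuron-like genes.

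The other 20 lists did not pass in this comparison (lowest camera adjusted p = 0.0533). Single members still differed, such as the autophagy receptor OPTN (1.94 and 2.17), the one-carbon gene ALDH1L2 (3.69 and 1.97) and the interferon-stimulated OAS3 (2.27 and 3.25). In the following counts the first number is of higher and the second of lower members in the mean of both lines, with the counts adjusted over the list alone in parentheses. They were 5 and 18 of 52 (6 and 20) for replication-dependent histones, 6 and 10 of 27 (8 and 13) for immediate early genes and 2 and 7 of 24 (2 and 7) for p53 targets. They were 5 and 4 of 27 (5 and 4) for ATF4 targets, 4 and 4 of 20 (4 and 4) for unfolded protein response targets and 5 and 3 of 23 (5 and 6) for autophagy genes. Members of these lists were DDIT4 (0.98 and 1.36), SRF (-0.72 and -1.35) and BTG2 (-0.39 and -0.78). They were 2 and 7 of 21 (2 and 7) for repeat-expansion disease genes, 3 and 2 of 78 (1 and 0) for cytosolic ribosomal proteins and 3 and 1 of 13 (3 and 1) for mitochondrially encoded mRNAs. They were 2 and 3 of 41 (1 and 1) for nuclear-encoded genes of oxidative phosphorylation, 5 and 7 of 27 (7 and 10) for cholesterol synthesis genes, 8 and 2 of 28 (9 and 3) for interferon-stimulated genes and 2 and 9 of 36 (4 and 12) for G2/M and mitosis genes. Members of these were MT-CO3 (0.65 and 0.64) and SQLE (-0.78 and -0.51). They were 8 and 3 of 21 (10 and 4) for SMAD/TGF-beta and matrix genes, 0 and 1 of 15 (0 and 1) for RNA polymerase III transcripts and 0 and 0 of 15 (0 and 0) for small nuclear RNAs. They were 2 and 2 of 19 (2 and 2) for long noncoding RNAs, 2 and 2 of 6 (2 and 2) for fibroblast markers, 0 and 0 of 5 (0 and 0) for blood and immune markers and 0 and 4 of 13 (0 and 4) for RNAi machinery genes. Members here were SPARC (1.32 and 1.94), LINC-PINT (1.40 and 1.35) and AGO2 (-0.51 and -0.46). Members that passed in each line singly with the same direction numbered, higher and lower, 2 and 3 for replication-dependent histones, 1 and 3 for immediate early genes, 0 and 2 for p53 targets, 4 and 1 for ATF4 targets, 0 and 0 for unfolded protein response targets, 5 and 0 for autophagy genes and 1 and 3 for repeat-expansion disease genes. They numbered 3 and 0 for cytosolic ribosomal proteins, 3 and 0 for mitochondrially encoded mRNAs, 2 and 1 for nuclear-encoded genes of oxidative phosphorylation, 2 and 3 for cholesterol synthesis genes, 3 and 1 for interferon-stimulated genes, 2 and 1 for G2/M and mitosis genes and 6 and 1 for SMAD/TGF-beta and matrix genes, and 0 and 0 for RNA polymerase III transcripts, 0 and 0 for small nuclear RNAs, 2 and 1 for long noncoding RNAs, 1 and 1 for fibroblast markers, 0 and 0 for blood and immune markers and 0 and 1 for RNAi machinery genes. Among blood markers, HBB measured 6.70 ± 2.45 and 5.59 ± 2.40 and did not pass, with high counts in 1 of the 2 scrambled libraries of each DARP line. Median and mean differed in sign for repeat-expansion disease genes (-0.09 and 0.02), and for mitochondrially encoded mRNAs and cholesterol synthesis genes the means were -0.003 and -0.003 beside medians of 0.16 and 0.08. Camera's direction for blood and immune markers was down beside a median of 0.08 and a mean of 2.12.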

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

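The tests of the spike-in mixes, of the ratio of mitochondrially encoded mRNAs as a sign of a common factor, of the treatment's effect on globin and of white cell markers were chosen only after the results were seen, as were the gene lists on the interaction, and the tests of subgroup membership and of white cell markers took the place of earlier ones, of which the latter was not scaled to library size, while the values of RNA per spike-in were planned and only the bounds they were held to were set after the results were seen. The tests of other red cell markers, of a globin-marked batch and of other splits of the libraries were written before their results.

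The ratios of the ERCC subgroups, which only the alternatives over all ERCC transcripts used, differed between knockdown and scrambled libraries by -1.95 ± 0.04 for A over B, 0.51 ± 0.06 for C over B and 0.80 ± 0.04 for D over B on the log2 scale (SE, n = 6 per treatment). The labelled mixes give 2.0, -0.585 and -1.0. An exchange of the treatment labels is argued against by SUPT4H1, at -3.80 in the libraries labelled knockdown. Wrong membership of subgroup A in the table used here is argued against as well, since the lowest transcript of the other subgroups lay 1.58 above the highest of subgroup A, while that of subgroup B stays open, with a difference of -0.014 between the lowest transcript of subgroup C and the highest of B. An exchange of the mix labels, or of the mixes in the table, stays open, with the -1.95 it needs, and no biological explanation was tested.

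Endogenous RNA per ERCC subgroup B count was lower in the knockdown libraries, with a log2 difference of -0.64, or 64.0% of the scrambled level. A few abundant features as the cause are argued against by a value of -0.59 without the 50 most abundant features, and 1 dominant spike-in transcript by -0.65 for the mean over transcripts. A factor common to all RNA classes would leave the ratio of mitochondrially encoded mRNAs to nuclear protein-coding genes unchanged. That ratio was 0.41 higher, but missed the threshold of the exact permutation test after adjustment over 6 ratios (0.0556). It was higher by 0.16 in the EGFP line, 0.785 in DARP line 1, which holds the library of lowest RIN, and 0.289 in DARP line 2. The ratio was chosen after the difference had been seen, so whether a common factor accounts for the smaller difference of mitochondrially encoded mRNAs stays open. For the whole difference of -0.64, less RNA per cell after SUPT4H1 knockdown and a difference in spike-in amount or cell number cannot be told apart, because the mix followed the treatment in every library.

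HBB counts were between 1846 and 3718 in all 6 knockdown libraries and in 2 scrambled libraries, and between 17 and 30 in the other 4. An effect of SUPT4H1 knockdown on globin is argued against by 3292 HBB counts in DARP line 1 scrambled replicate 2. Other red cell markers were between 130 and 284 counts in the libraries with high HBB and between 6 and 10 elsewhere, and RNA or reads of red cells or another globin-rich sample may be the source, while blood with its white cells stays open, since white cell markers differed by 0.084 ± 0.070 CPM (SE) between the 8 libraries with high HBB and the other 4. A library batch that globin marks is argued against for the knockdown changes shared by the lines, since 1703 genes called in the EGFP line from its own libraries kept a fraction of 1.075 of their median signed log2 fold change in the 6 DARP libraries with high HBB (0.38, against 0.35 in all 8). Within the EGFP line, high HBB and knockdown coincide and cannot be separated.

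Of 100 splits of the 12 libraries into 6 and 6, with line as a term, the real one gave 5470 genes and the highest of the others 3, so 1 of 100 gave as many and a random grouping is argued against. The other splits leave the knockdown effect in the residual spread, so the gap between 5470 and 3 does not measure its size. The real split is also that of the spike-in mixes, which the splits cannot separate from the siRNA.

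Among 34 groups of 6 libraries examined, 3 values, from 2 libraries, stood far from the others of their treatment, where about 1 group in 20 does by chance. DARP line 1 knockdown replicate 2 had the lowest log2 ratio of ERCC subgroup C over B among knockdown libraries, 0.65, with a gap to the next of 0.636 of the range. The same library had the highest SUPT4H1 level among them, 3.31 CPM, with a gap of 0.833 of the range. DARP line 2 knockdown replicate 1 was the deepest of them, with 75253642 counts and a gap of 0.631 of the range.

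The knockdown response differed between the DARP lines and the EGFP line in 9 lists by camera (5 without the 2 knockdown libraries of lowest RIN), with median differences of 0.21 for RNA polymerase I and III subunits, 0.17 for cytosolic heat shock genes, 0.27 for RNA-binding proteins linked to ALS, -0.25 for cytosolic ribosomal proteins, 0.18 for ribosome biogenesis, 0.56 for mitochondrially encoded mRNAs, -0.20 for nuclear-encoded oxidative phosphorylation, -0.58 for RNA polymerase III transcripts and -0.96 for spliceosomal and U7 small nuclear RNAs. The lowest adjusted p with an estimated correlation was 0.557, and 0 lists had an unadjusted p under 0.05 there. The EGFP feature differed by 0.70 ± 0.25 (1.29 ± 0.29 on the spike-in scale) between these responses (edgeR adjusted p = 0.38 over all genes), with at least 749 counts in each library of the EGFP line.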

How the results depend on the processing

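The alternatives that left out libraries of low RIN, DARP line 1 or libraries with high HBB counts, that kept only the DARP libraries with high HBB counts, or that used GC content, reversed mix ratios, the interaction lists or a replicate block for the rho with length were chosen after seeing the data; the others were planned. For the mean of the lines, DESeq2 gave 6082 genes, limma-voom 6137, DESeq2 size factors 6184, no filter 4793, RIN as a covariate 5314 and libraries left out in turn 4339 to 5872, beside 6149. A log2 fold change of at least 1 gave 466 genes there, 201, 333 and 498 in the EGFP line and DARP lines 1 and 2, 490 for the DARP lines against the EGFP line and 2639 on the ERCC scale. ERCC subgroup B scaling gave 12460 genes, all ERCC transcripts at the labelled mix ratio 19039 and at the reversed ratio 10715. RNA per spike-in was -1.325 at the labelled and -0.547 at the reversed ratio, beside -0.644. The subgroup ratios ran opposite to the labelled mixes, which limits the values at the labelled ratio. The 6 DARP libraries with high HBB counts gave 1 gene by edgeR with 2 residual degrees of freedom (4564 at an unadjusted p under 0.05). Without a filter, more genes were tested and 854, 1192 and 1642 passed in the EGFP line and DARP lines 1 and 2, and 3 in the interaction. DESeq2 gave 2573 in the EGFP line and 282 in the interaction, and RIN as a covariate 1266 in DARP line 1. With fewer libraries, counts were 502 and 453 in the EGFP line and DARP line 1 without the low-RIN libraries, 2852 and 4424 in the EGFP line and DARP line 2 and 1 in the interaction without DARP line 1, and 0 in DARP line 1 by edgeR from its own 4 libraries (2967 at an unadjusted p under 0.05). Without the 2 scrambled libraries with high HBB counts they were 967, 1212 and 439 in the lines, 3 in the interaction and 1345 for the DARP lines against the EGFP line. Libraries left out in turn gave 79 to 1927 genes in the EGFP line, 508 to 2091 in DARP line 1, 347 to 3186 in DARP line 2, 0 to 3 in the interaction, 899 to 2674 for the DARP lines against the EGFP line, 8494 to 15026 on the ERCC scale, -0.69 to -0.60 for RNA per spike-in, 7 to 11 lists for knockdown, 11 to 14 for the DARP lines, 6 to 13 for the interaction, and a rho with length of -0.013 to 0.023. Where 1 library of a group remains, it is assumed to vary like the other groups. Without the 2 scrambled libraries with high HBB counts, HBB was high in every knockdown library and in no scrambled library. In the knockdown contrasts that alternative therefore cannot separate HBB counts from treatment. With an estimated correlation 0 of the 8 knockdown lists, 0 of the 11 lists of the DARP lines and 0 of the 9 interaction lists passed (4, 1 and 0 at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, gave 14, 17 and 0 lists in 1 direction (5 of the last at an unadjusted p under 0.05) and 29, 27 and 1 in either, and 5 interaction lists passed without the low-RIN libraries. The partial rho with length given GC content was -0.082. Where the construction of an alternative does not show it, the cause was not tested.

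With the replicate number as a block, which uses residual degrees of freedom, 27, 60 and 520 genes passed in the EGFP line and DARP lines 1 and 2 and 7005 on the ERCC scale. It gave 4135 for the mean of the lines, 0 in the interaction by edgeR (1760 at an unadjusted p under 0.05), 2248 for the DARP lines against the EGFP line, 8, 11 and 9 lists, -0.64 for RNA per spike-in and a rho of 0.005. Same-numbered libraries did not deviate together (correlations -0.019, -0.112 and 0.071), which gave no sign of pairing. With 2 libraries per group, pairing cannot be excluded, and the labels do not say how replicates were made.

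Of 301 results for single genes, 275 passed the threshold and 82 of these fell short of it without at least 1 library, and 0 reversed when a library was left out. DESeq2 left 288 of 298 on the same side of the threshold, limma-voom 295 of 301, DESeq2 size factors 300 and the block 274. On the ERCC subgroup B scale, 68 of 117 kept direction and side, 11 kept direction only, and 38 reversed, since that scale shifts the median gene by -0.583 (-1.006 in the EGFP line, -0.348 and -0.397 in DARP lines 1 and 2): SUPT5H -0.552, C9orf72 -0.499, EGFP -0.416, HEXIM1 -0.082, CTR9 -0.139, POLR2L -0.013, POLR2K -0.154, POLR1C -0.289, POLR3A -0.296, ATF5 -0.138, CALR -0.132, SEC61B -0.159, HSPH1 -0.048, PSMD12 -0.003, PSMB4 -0.208, SMCR8 -0.052, NUP214 -0.19, NUP98 -0.314, MATR3 -0.324, CSTB -0.321, ATXN10 -0.354, RPL28 -0.056, RPS20 -0.052, UTP4 -0.307, NDUFB3 -0.136, ATP5C1 -0.163, ACAT2 -0.124, ALDOC -0.027, HERC6 -0.141, PCNA -0.181, CDC6 -0.197, PTTG1 -0.225, SNHG5 -0.106, TUG1 -0.143, TUBB3 -0.162, CORO1A -0.104, TNRC6A -0.233 and TNRC6C -0.264. The first 3 of these passed the threshold on that scale only.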
